A study of Mus musculus with 4 samples.

How the data were processed

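The data are gene-level values of 4 RNA sequencing libraries of sorted splenic NK cells, 1 for each combination of genotype label and injection. The authors deposited whole-number read counts per gene, not normalized, and the deposited FPKM values beside them. Per the submitters' processing notes the tools were TopHat and edgeR and the genome build was mm10, with no versions; the counting tool, the gene annotation and whether counting used strand are not given in the sources used here. Reads of overlapping, antisense or near-identical genes therefore cannot be assigned with certainty. Per the labels' protocols, NK cells were enriched with a kit, sorted, and made into libraries with a SMARTER mRNA kit. The deposited FPKM values equalled the count divided by the library total and a whole-number gene length, to within 0.01 bp, for all 72455 values with a count.

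The tables held 35275 gene identifiers, of which 34490 matched a symbol in the GENCODE annotation of GRCm38, the assembly that mm10 denotes, and 785 did not; 21484 had a count in any library. Genes with no matched symbol held between 0.0871% and 0.0887% of the counts, depending on the library. Groups were taken from the sample titles and the series design text, in which treated means injected. Every value column belonged to a sample of known group.

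Counts were scaled by trimmed mean of M values (TMM) in edgeR 4.0.16 on R 4.3.3. In each of 4 pairs of libraries a log2 ratio of CPM, counts scaled to the library size, was computed with a prior count of 2. A gene was counted as higher or lower when its mean was at least 5 CPM over the 2 libraries, the ratio at least 2-fold and the exact (Clopper-Pearson) 95% counting interval of the ratio excluded 1. This is a rule of size, not a test. The tested results come from edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided, not robust) with genotype and injection as additive terms over all 4 libraries, for genes with at least 1 CPM in at least 2 libraries, with Benjamini-Hochberg adjustment at 0.05. It has 1 residual degree of freedom, a prior of 9.62 degrees of freedom and a common dispersion of 0.00996, a biological coefficient of variation of 9.98%. The labels do not say how many animals were behind a library, so the spread behind the p-values is only how far these libraries depart from additivity, which may be technical. Standard errors were obtained as the size of the log2 change divided by the square root of F. "Rose" and "fell" are used of this test alone.

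Each gene list was summarised by its median log2 ratio over members with a mean of at least 1 CPM over the 4 libraries, with the place of that median among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with fewer than 5 such members have values only. The 35 lists held 751 entries, of which 740 matched by symbol, 2 by synonym and 8 not at all, and 1 repeated another of its list. Several genes stand in more than 1 list. Of the markers of other cells, some, such as Itgax and Irf8 of the dendritic cell list, are also expressed by NK cells.

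Genes named in the text follow a rule. Irf4 is always named. Among protein-coding genes with a mean of at least 5 CPM, leaving out immunoglobulin and T cell receptor segments and predicted genes, the largest log2 ratios in each direction are named, 10 for genotype in injected mice and 6 for each other pair. The rule adds up to 4 members of each list per pair, the 6 largest passing changes in each direction per additive effect and the 5 largest differences of response in each direction. Some were left out for length, 1 gene is not reported here, and genes outside the rule are said to have been chosen after their values were seen. Groups, tests, lists, this rule and most alternatives were fixed before the data were examined.

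Both steps were tested on simulated data with 200 changed genes and a dispersion of 0.01. For genotype in injected mice the 2-fold rule found 86.0% of 100 genes changed 2.5-fold and 98.0% of 100 changed 4-fold, and 0 of 9463 unchanged genes, among 9663 genes. For the genotype effect the additive model found 100 of 100 genes at either size and 11 of 11729 unchanged genes, among 11929 genes. Every simulated gene had the same dispersion, near the 0.00996 estimated here. There was no injection effect, no response that differed between genotypes and no library that stood apart. These rates therefore check the steps on data that meet the model, and do not give the rates in the real libraries.

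At these depths 3 counts correspond to 0.142 CPM in WT control, 0.161 in WT injected, 0.189 in Irf4-/- control and 0.161 in Irf4-/- injected, the limit that a count of 0 allows. Alternatives were median-of-ratios, upper-quartile or total scaling, other minimums, folds and prior counts, FPKM with a pseudocount of 0.1, abundant gene families left out, no filter or a 5 CPM filter, an adjusted p under 0.1, the other term left out, DESeq2 1.42.0 and limma-voom in limma 3.58.1. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.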

Results

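Gene expression was measured by bulk RNA sequencing in natural killer (NK) cells, innate lymphocytes that kill tumour and virus-infected cells, sorted from mouse spleen as CD3-negative, NK1.1-positive cells. The mice were wild type (WT) or carried the label Irf4-/-, a knockout of the transcription factor IRF4. Mice of each genotype had either received B16-F10 cells, a mouse melanoma line, into a vein 20 days before or had not been injected. There were 4 groups with 1 library each, and the total counts were 21104881 in WT control, 18640811 in WT injected, 15878159 in Irf4-/- control and 18639455 in Irf4-/- injected. Because no group had a replicate, a difference between 2 libraries compares those libraries, not the conditions, and carries no p-value. The 95% intervals given with pairwise log2 ratios cover counting error only and treat each read as an independent draw. PCR reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error.

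Irf4, the targeted gene (ENSMUSG00000021356, chromosome 13, 30749226 to 30766976 in GRCm38), had 93 counts in WT control, 57 in WT injected, 188 in the library labelled Irf4-/- control and 236 in the library labelled Irf4-/- injected. Scaled to library size (CPM), these are 4.43, 3.07, 11.7 and 12.7. Irf4 was therefore higher in the libraries labelled Irf4-/-, with a log2 ratio of 2.01 (1.62 to 2.49) in the injected pair and 1.39 (1.04 to 1.78) in the control pair. Fewer counts might be looked for under a knockout label. However, the labels do not say which part of the gene was deleted. Counts summed over the whole gene can therefore neither bear the label out nor contradict it. Every genotype direction below is that of the library labelled Irf4-/- relative to WT and depends on those labels.

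The comparison of genotypes in injected mice asked how NK cells of mice given B16-F10 cells and labelled Irf4-/- differed from those of WT. The library labelled Irf4-/- held more transcript of Cx3cr1, the fractalkine receptor of mature NK cells, with a log2 ratio of 3.07 (2.93 to 3.21), and of Il10, an anti-inflammatory cytokine, with 4.02 (3.51 to 4.85). It held less of Pik3ip1, an inhibitor of phosphoinositide 3-kinase, at -4.88 (-5.27 to -4.58), of Socs2, a suppressor of cytokine signalling, at -3.59 (-3.99 to -3.29), and of Camk2b, a calcium and calmodulin dependent kinase subunit, at -3.58 (-3.88 to -3.33). Cell cycle genes were higher as a group, in 36 of 38 members by their counting intervals, and so were 12 of 14 late maturation genes. Of 9685 genes with a mean of at least 5 CPM, 110 were at least 2-fold higher and 64 at least 2-fold lower in the library labelled Irf4-/-.

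Among the other large ratios in the injected pair, Ano7 stood at 5.56 (4.67 to 9.60) from 2 and 187 counts, the trafficking protein gene Nbea at 4.37 (3.88 to 5.18), the hydroxylase gene Asph at 3.59 and the titin gene Ttn at 3.36. Ly6a, which encodes the surface antigen Sca-1, was at 2.97, the cyclic GMP phosphodiesterase gene Pde5a at 2.72 and the beta globin gene Hbb-bs at 2.67. The interferon-inducible gene Ifi211 was higher at 2.69 and its family member Ifi208 lower at -2.50; reads of such near-identical copies may be split between them. The peptide transporter gene Slc15a2 was lower at -2.46, the linker histone gene Hist1h1e at -2.43, Card14 at -2.26, Trnp1 at -2.19, the Notch coactivator gene Maml3 at -1.97 and Ccdc28b at -1.88.

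In the cell cycle list the median log2 ratio in the injected pair was 0.66 (0.50 to 0.84 over genes), and 36 of 38 members had counting intervals above 0. Of 10000 random lists matched on expression 0 had a median as high, and in the same pair 0 were as high as the B cell median and 1 was as low as the monocyte and macrophage median. Rrm2, a ribonucleotide reductase subunit, was at 1.23 (1.05 to 1.43), the DNA methylation factor Uhrf1 at 1.07, the mitotic kinesin Kif20a at 1.06 and the replication licensing factor Cdc6 at 1.02. The late maturation list had a median of 0.45, with 12 of 14 intervals above 0, led after Cx3cr1 by Klrg1 at 1.63 (1.54 to 1.72), the chymase gene Cma1 at 0.91 and the integrin gene Itgam at 0.83. The early maturation list had a median of 0.01, with Xcl1 at 0.89 and Emb at -0.60.

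The list of type 1 innate lymphoid or tissue-resident genes had a median of 0.26 (-0.128 to 1.034 over genes, which includes 0). In that list the chemokine receptor gene Cxcr6 was at 2.25 (2.04 to 2.48) and the integrin gene Itga1 at 1.44. Zfp683, which encodes the residency factor Hobit, was at 1.03. Among inhibitory genes Cd200r1 was at 1.45 and the checkpoint receptor gene Lag3 at 1.07, while Nr4a1 was at -0.90 and Cish at -0.93, and the list median was -0.07. Il2ra, the alpha chain of the interleukin 2 receptor, was higher at 1.77 (1.52 to 2.04), and Cxcr4, a receptor for the chemokine CXCL12, lower at -1.70 (-1.77 to -1.63). The endoplasmic reticulum stress list had a median of 0.38, with 17 of 20 intervals above 0 and Calr, which encodes calreticulin, at 0.97. Summed CPM of that list was 2886 in WT injected, against 3692 in WT control, 3665 in Irf4-/- control and 3833 in Irf4-/- injected. The antiapoptotic gene Bcl2 was at -1.04 and the proapoptotic genes Bbc3 and Bcl2l11 were at -0.89 and -0.68. Tnfsf10, which encodes the death ligand TRAIL, was at 1.16 and perforin, Prf1, at 0.53, while the cytotoxic list as a whole had a median of 0.08 and the NK receptor list one of -0.02. The interferon response list had a median of 0.04. In the same pair the B cell list had a median of 0.49 (0.363 at a minimum of 20 CPM) and the T cell list one of -0.03. The monocyte and macrophage list had one of -0.43 (-0.554 to 0.009 over genes, which includes 0), or -0.197 at that minimum. The erythroid list was at 0.40 (-0.571 to 2.543 over genes, which includes 0) and Igkc, in the B cell list, at -1.57 (-2.12 to -1.12). The plasma cell list (6 members, of which 2 had a mean of at least 5 CPM in this pair) was at -1.05. Its interval over genes, -3.701 to 0.553, includes 0, and the median was 0.180 at a minimum of 20 CPM from few genes. The WT injected library stood farther from each other library than any pair without it.

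**Figure D1:**
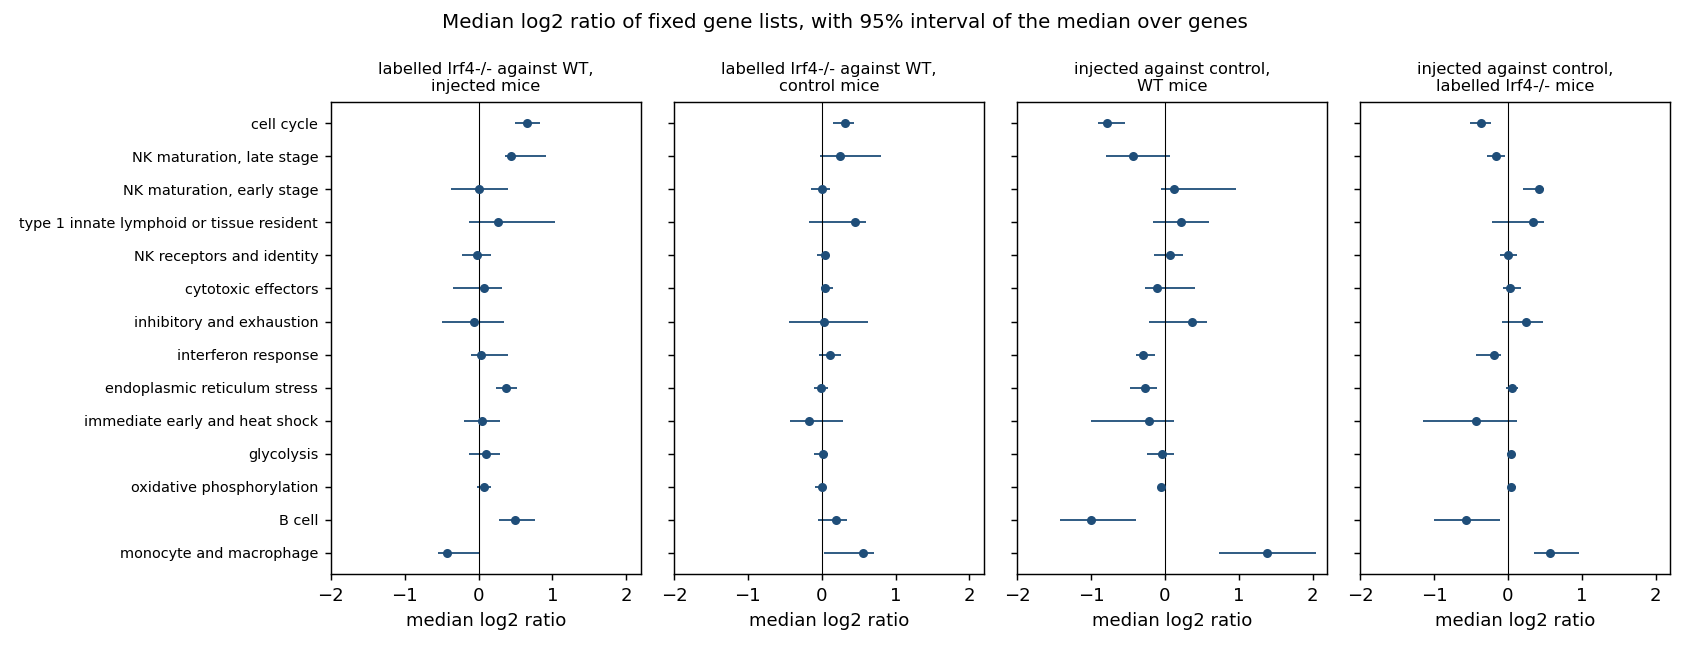
Median log2 ratio of 14 of the gene lists (rows) in each of the 4 pairs of libraries (panels); points are medians over genes and bars their 95% interval over genes, not over mice. The cell cycle median is 0.66 and 0.32 in the panels of the genotype pairs, and -0.79 and -0.37 in the panels of the injection pairs.

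In control mice the genotype comparison asked how NK cells labelled Irf4-/- differed from WT without tumour cells. Nbea was at 3.83, Ifi211 at 2.62, Ttn at 2.46, the semaphorin gene Sema6d at 2.40, Asph at 2.31 and P2rx7, an ATP-gated ion channel, at 2.22. Camk2b was at -2.79, Pik3ip1 at -2.50, Ifi208 at -2.31 and Emid1 at -1.62. The near-identical inducible heat shock genes Hspa1a and Hspa1b, whose reads may be shared, were at -2.09 and -2.03. Of 9659 measured genes 67 were at least 2-fold higher and 10 at least 2-fold lower.

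Late maturation and cell cycle genes were higher in the control pair too. Cx3cr1 was at 1.63 (1.54 to 1.72), Klrg1 at 1.14 and Cma1 at 0.80, in a late maturation list with a median of 0.25 (-0.03 to 0.80 over genes, which includes 0), with 11 of 14 intervals above 0 and 1 below. The cell cycle median was 0.32, with 23 of 38 intervals above 0 and 2 below, led by the mitotic kinase Aurkb at 0.86 and the cyclin gene Ccnb1 at 0.76. Il2ra was at 2.18 (1.85 to 2.59), Cxcr6 at 1.84 (1.60 to 2.12), Cd200r1 at 1.17, Lag3 at 0.99 and Nr4a1 at -0.65. Tcf7, a transcription factor of early lymphoid stages, was at -0.62. The endoplasmic reticulum list, at 0.38 in the injected pair, had a median of -0.01 in the control pair. Here the monocyte and macrophage list stood at 0.57 (-0.264 at a minimum of 20 CPM), the B cell list at 0.20 and the dendritic cell list at 0.205 (-0.038 at that minimum). The intervals over genes of the B cell list (-0.055 to 0.346) and the dendritic cell list (-0.049 to 0.394) include 0.

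The genotype pairs share no library. Over 9674 genes their log2 ratios had a Pearson correlation of 0.451 and a Spearman correlation of 0.212 across genes, which are not independent replicates. At least 2-fold higher in both pairs were 43 genes, where independent lists would share 0.694, and 6 were lower in both, against 0.039, and 0 genes went opposite ways.

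**Figure D2:**
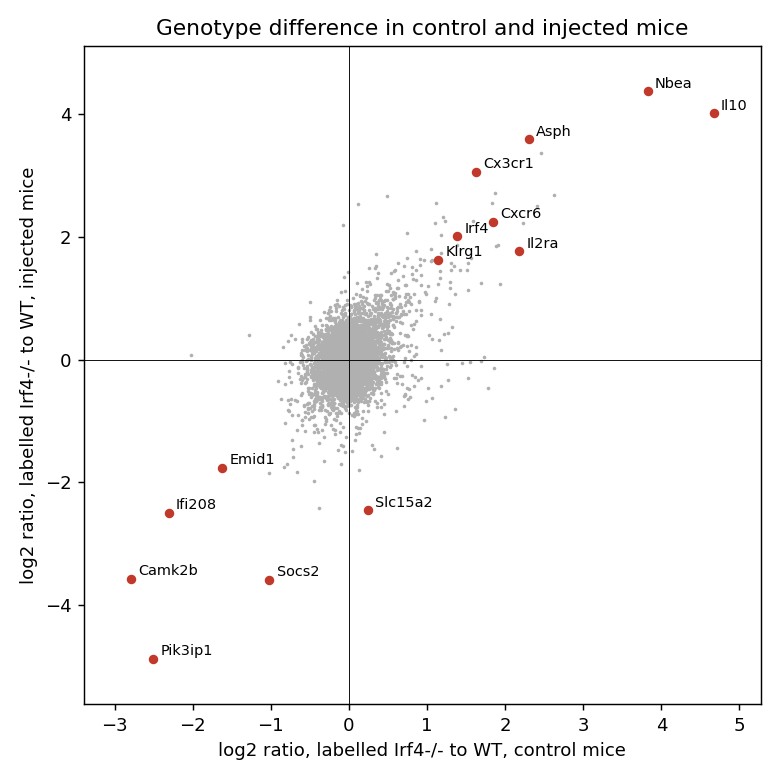
Log2 ratio of the library labelled Irf4-/- to WT in control mice (horizontal axis) and in injected mice (vertical axis), with 1 point per gene and some named genes in red. Nbea lies at 3.83 and 4.37 and Camk2b at -2.79 and -3.58, whereas Slc15a2 lies at 0.24 and -2.46.

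With genotype and injection as additive terms over all 4 libraries, 146 genes rose and 31 fell with the Irf4-/- label among 11998 tested (261 and 113 with median-of-ratios scaling, 319 and 163 with no filter, 119 and 15 with DESeq2, 142 and 30 with limma-voom). Il10 rose by 4.45 on the log2 scale (SE 0.327, adjusted p 6.93e-05), Nbea by 4.29 (SE 0.258, adjusted p 1.82e-05) and Asph by 3.01 (SE 0.274, adjusted p 0.000288), from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Grhl3, a transcription factor of epithelia, rose by 5.13 (SE 0.515) from 1 and 4 counts in WT to 38 and 132, and the nucleoside enzyme gene Upp1 rose by 3.18 (SE 0.504). Nefh, a neurofilament gene, fell by 4.22 (SE 0.470), Pik3ip1 fell by 3.87 (SE 0.401), Camk2b fell by 3.14 (SE 0.171), Ifi208 fell by 2.41 (SE 0.136) and Lrmda fell by 2.23 (SE 0.381). Irf4 itself rose by 1.72 (SE 0.241). Ano7, with 4.19, and Socs2, with -2.35, passed this test but not the DESeq2 Wald test, where their adjusted p was 0.143 and 0.826.

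Of the late maturation list 4 of 14 genes rose with the genotype label, namely Cx3cr1, Klrg1, Cma1 and Itgam, and none fell, while adjusted over the list alone 8 rose and 1 fell. Cx3cr1 rose by 2.32 (SE 0.247), Klrg1 by 1.39 (SE 0.123), Cma1 by 0.86 and Itgam by 0.67. Of 39 cell cycle genes 4 rose, which were Mki67 with 0.68, Top2a with 0.69, Tpx2 with 0.78 and Rrm2 with 0.85, and adjusted over the list alone 24 rose and 0 fell. Beside this, summed CPM of the cell cycle list was 1552 in WT injected, the library that stood apart, against 2315 in WT control, 2650 in Irf4-/- control and 2186 in Irf4-/- injected, and the B cell list had a genotype median of 0.27, with Cd74 rising. Tpx2 had an adjusted p of 0.113 by DESeq2 and 0.0519 by limma-voom. Among 31 interferon response genes 4 rose, including Ifit2 by 0.58, Gbp3 by 0.63 and Iigp1 by 2.40, and adjusted over the list alone 8 rose; Ifit2 had an adjusted p of 0.122 by DESeq2. Cxcr6 rose by 2.07 as the 1 call in its list of 13 genes (4 adjusted over the list alone), and Il2ra rose by 1.98 in a receptor list where 2 of 24 genes rose (3 adjusted over the list alone). In the inhibitory list of 15 genes Lag3 rose by 1.04, Cd200r1 rose by 1.35 and Nr4a1 fell by 0.77, and adjusted over the list alone 4 rose and 4 fell. Mki67, Top2a, Tpx2, Ifit2 and Iigp1 were chosen after their values were seen. No gene of the glycolysis list (21 tested) or the oxidative phosphorylation list (43 tested) passed, over all genes or adjusted over the list alone (0 in each). The model has 1 residual degree of freedom, counts any interaction as error and does not measure the spread between animals. With injection left out as a term 3 genes rose and 2 fell.

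Along chromosome 11 the genotype calls crowded near the start, a feature chosen after the values were seen. Between 3131850 and 6200415 in GRCm38, 12 of 54 tested genes passed, 6 higher and 6 lower, and the densest such 3 Mb window on any other chromosome held 4. Besides Pik3ip1, Nefh and Camk2b these included Emid1, which fell by 1.69 (SE 0.116), and the transporter gene Slc35e4, chosen in the same way, which rose by 1.56 (SE 0.167).

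**Figure D3:**
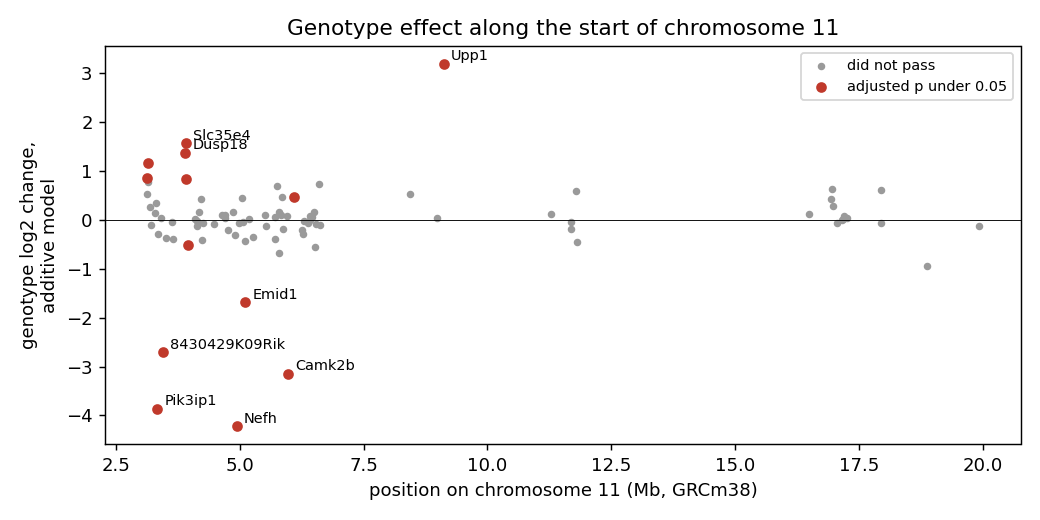
Genotype log2 change of each tested gene in the additive model (vertical axis) by its start on chromosome 11 in Mb of GRCm38 (horizontal axis), with genes at adjusted p under 0.05 in red and the others in grey. Of the 54 tested genes between 3131850 and 6200415, 12 are red, 6 above and 6 below 0.

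In WT mice the injection comparison asked how NK cells of the spleen differed 20 days after B16-F10 cells were given. The inducible heat shock genes Hspa1b and Hspa1a were lower in the injected library, with log2 ratios of -6.53 (-7.43 to -6.01) and -6.18 (-10.22 to -5.30, from 325 and 2 counts), and the chaperones Hsph1 and Hsp90aa1 were at -2.20 and -1.54. Cell cycle genes were lower as a group, with a median of -0.79 and 35 of 38 intervals below 0. The WT injected library, which stood apart, had 5.97% of counts in ribosomal protein genes and 1.14% in mitochondrial genes, against 4.32% to 4.82% and 0.905% to 0.976% in the others, and the fewest genes with a count (17678). The interleukin 7 receptor gene Il7r was higher at 1.69 (1.60 to 1.78) and the inhibitory receptor gene Tigit at 1.5 (1.37 to 1.63). Irf4 itself was at -0.51 (-1.03 to -0.04). Of 9638 genes 102 were at least 2-fold higher and 80 at least 2-fold lower.

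The largest ratios upward in the WT pair were those of Trnp1 at 5.77 (4.97 to 9.90, from 2 and 203 counts), the phospholipase gene Plcd3 at 3.96, the adhesion molecule gene Vcam1 at 2.60, Pik3ip1 at 2.31, Dmrta1 at 2.02 and Socs2 at 1.96. Of these, Vcam1 is a member of the monocyte and macrophage list. Rhpn1 was at -1.79 and Cchcr1 at -1.58. In the cell cycle list Cdc6 was at -1.51, Uhrf1 at -1.25, Rrm2 at -1.24 and the mitotic kinase Cdk1 at -1.17. The late maturation list had a median of -0.43 (-0.796 to 0.074 over genes, which includes 0), with 11 of 14 intervals below 0 and 1 above. In that list Cx3cr1 was at -1.47 (-1.63 to -1.32), Klrg1 at -0.80 and the egress receptor gene S1pr5 at -0.62. Among early maturation genes Emb was at 0.97 and the stem cell factor receptor gene Kit at 0.96. Interferon response genes had a median of -0.29, with Oas3 at -1.28 and Ifit3 at -1.02. The endoplasmic reticulum list had a median of -0.28, with Calr at -0.89. This pair shares the WT injected library with the genotype pair of injected mice. Values of opposite sign in those pairs, here and for other genes and lists, are therefore not separate observations. Rab27a, needed for granule release, was at 1.16, and Pdk1, a kinase that inhibits pyruvate dehydrogenase, at 1.08. Bcl2l11, Bbc3 and Bcl2 were at 1.02, 0.89 and 0.86. Beside these groups the monocyte and macrophage list stood at 1.39 (0.044 at a minimum of 20 CPM), with Slc40a1 at 1.78, Hmox1 at 1.67 and Lyz2 at -1.33, and the B cell list stood at -1.01 (-0.270 at that minimum), with Cd79a at -1.36. The platelet and megakaryocyte list (6 members, of which 3 had a mean of at least 5 CPM in this pair) was at 1.003 (0.541 at that minimum). The erythroid list was at -0.525 (-0.202 at that minimum), with an interval over genes of -1.022 to 0.424, which includes 0.

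The injection comparison in mice labelled Irf4-/- asked the same of the other genotype. Hspa1b was at -4.43 (-5.32 to -3.91) and Hsph1 at -1.22, and the immediate early genes Fosb and Dusp1 were at -2.28 and -1.44. Ano7 was at 1.49, Il10 at 1.40, Vcam1 at 1.34, and the globin genes Hbb-bs, Hbb-bt and Hba-a1, whose reads near-identical copies may share, at 1.33, 1.29 and 1.26. Slc15a2 was at -1.76, Fbxl22 at -1.74 and Camk2b at -1.41. Of 9697 genes 13 were at least 2-fold higher and 21 at least 2-fold lower. The cell cycle median was -0.37 with 31 of 38 intervals below 0, the late maturation median -0.16 and the early maturation median 0.42, led by Il7r at 1.18 and Kit at 0.80. Tigit was at 0.88, Cxcr6 at 0.85 and granzyme B, Gzmb, at -0.60. The monocyte and macrophage list stood at 0.57 and the B cell list at -0.57, or 0.111 and -0.068 at a minimum of 20 CPM. The plasma cell list (6 members, of which 2 had a mean of at least 5 CPM in this pair) was at -2.185. Its interval over genes, -4.091 to 0.16, includes 0, and the median was 0.076 at that minimum from few genes. The list of other innate lymphoid cells was at 0.325 (-1.504 to 1.183 over genes, which includes 0), or 0.204 at that minimum. Irf4 was at 0.11 (-0.17 to 0.40). With the other-cell and heat shock lists left out, an alternative chosen after seeing the data, 8 genes were at least 2-fold higher and 13 lower.

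Between the injection pairs the Pearson correlation over 9674 genes was 0.444 and the Spearman correlation 0.366. Shared calls were 3 higher, against 0.055 from independent lists, and 7 lower, against 0.146, and 1 gene went opposite ways.

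In the additive model 40 genes rose and 47 fell with injection, among 11998 tested (230 and 228 with median-of-ratios scaling, 305 and 299 with no filter, 33 and 39 with DESeq2, 38 and 37 with limma-voom). Irf4 did not pass, at -0.16 with an adjusted p of 0.804. Hspa1b fell by 5.80 (SE 0.327, adjusted p 3.66e-05), Hspa1a fell by 5.98 (SE 0.513, adjusted p 0.000523) and Hsph1 fell by 1.70 (SE 0.181, adjusted p 0.00212) in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Fbxl22 fell by 1.94 (SE 0.290), while Plcd3 rose by 2.91 (SE 0.451) and Vcam1, of the monocyte and macrophage list, by 2.0 (SE 0.290). Several other large values passed this test but not DESeq2, whose adjusted p was 0.396 for Trnp1 with 4.39, 0.144 for the mineralocorticoid receptor gene Nr3c2 with 2.25, 0.121 for Thsd7b with 2.11, 0.113 for the complement gene C1qc with 1.78, 0.107 for the B cell gene Fcer2a, which encodes the IgE receptor CD23, with -2.28 and 0.156 for the IgM receptor gene Fcmr with -2.18. In limma-voom the adjusted p was 0.0509 for Trnp1, 0.0582 for Nr3c2, 0.0607 for Fcer2a and 0.0509 for Fcmr.

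By list, 6 of 22 immediate early and heat shock genes fell with injection, all of them heat shock genes. Among them were Dnajb1, at a log2 of -1.35, Hsp90aa1 at -1.14 and Hspa8 at -0.77. Adjusted over the list alone 9 fell and 1 rose. Hsp90aa1 had an adjusted p of 0.220 by DESeq2. Of 39 cell cycle genes 4 fell, with Mki67 at -0.65, Top2a at -0.78, the spindle motor gene Kif11 at -0.72 and Rrm2 at -0.85, and adjusted over the list alone 31 fell; Rrm2 had an adjusted p of 0.0618 by limma-voom. In the early maturation list Il7r rose by 1.44 (SE 0.127), Kit by 0.88 and Emb by 0.73, 3 of 16 genes, with 5 adjusted over the list alone. None of the 14 late maturation genes passed over all genes (0), while 6 fell adjusted over the list alone. Tigit rose by 1.20 (SE 0.148), 1 of 15 inhibitory genes with 6 adjusted over the list alone, and Rab27a rose by 0.91, 1 of 22 cytotoxic genes and 1 adjusted over the list alone. In the B cell list 2 of 21 genes fell, and 11 adjusted over the list alone. In the monocyte and macrophage list 2 of 20 rose, C1qc and Vcam1, and Lyz2 fell by 1.26, with 12 rising and 1 falling adjusted over the list alone. Dnajb1, Hspa8 and Kif11 were chosen after their values were seen. With genotype left out as a term 0 genes passed in edgeR, against 1091 at an unadjusted p under 0.05 and 0 in limma-voom.

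How far the injection response differed between genotypes is a value with no test, because a model with an interaction leaves no residual degrees of freedom. Of 9674 genes 46 had a response at least 2-fold higher, and 77 at least 2-fold lower, in mice labelled Irf4-/- than in WT. The globin genes Hba-a1, Hbb-bt and Hbb-bs differed by 2.42, 2.27 and 2.18 on the log2 scale, Hspa1b by 2.10 and the Notch target gene Hes1 by 1.69. In the other direction Slc15a2 differed by -2.70, Socs2 by -2.58, Pik3ip1 by -2.38, the laminin gene Lamb3 by -2.18 and Plcd3 by -2.16. Pik3ip1 went from 24.2 to 120 CPM in WT and from 4.18 to 3.97 in the libraries labelled Irf4-/-.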

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

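Of the tests below, the 1 on the remaining genes of the chromosome 11 stretch was set before its result was seen, and the other 10 tests were chosen only after the results were seen.

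For 10 named genes the response to injection went opposite ways in the genotypes, or the genotype ratio went opposite ways in the control and injected pairs, with counting intervals that exclude 0 on either side and both ratios at least 1.5-fold. These differences were not tested, and genotype directions depend on labels that the Irf4 counts cannot check. Of these, Trnp1 differed most between genotypes, by -3.77 on the log2 scale, with a response of 5.77 in WT and 1.99 in mice labelled Irf4-/-. Its counts were 2 and 203 in WT control and injected and 8 and 43 in the libraries labelled Irf4-/-, so its control values rest on few counts. Trnp1 and Ano7 lie below the mean of 5 CPM over the 4 libraries that the differences of response above required. Ano7 differed by 3.05, from -1.55 in WT to 1.49. The globin genes differed by 2.42 for Hba-a1, 2.18 for Hbb-bs and 2.27 for Hbb-bt, each lower in WT injected than in WT control and higher in the library labelled Irf4-/- injected than in its control. Slc15a2 differed by -2.70 (0.94 in WT, -1.76 in mice labelled Irf4-/-) and Socs2 by -2.58 (1.96 and -0.62). The chemokine receptor gene Cxcr4 differed by -1.60 (0.71 and -0.89). The immediate early genes Dusp1 and Fosb differed by -2.05 and -1.94, with genotype ratios of 0.61 and 0.96 in the control pair and -1.44 and -0.98 in the injected pair. The monocyte and macrophage list had a genotype median of 0.57 in the control pair and -0.43 in the injected pair, a difference of -0.997 that was not tested either. At a minimum of 20 CPM the control median was -0.264 and the injected one -0.197, so the medians no longer went opposite ways. Summed CPM of the list was 704 in the library labelled Irf4-/- control against 799 in WT control. Without the 1.5-fold cut 26 of 200 named genes had opposite intervals for genotype and 34 of 184 for injection.

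Genotype calls crowded at the start of chromosome 11, with 12 in a 3 Mb window, where 10000 random placements of the calls gave at most 9. A segment kept around Irf4 was argued against, as Irf4 lies on chromosome 13 with 1 other call within 10 Mb (percentile 24.6 of 1000 windows). A candidate explanation is a segment that differs between the animals behind the genotype labels. Of the 57 genes of the first 10 Mb that did not pass, 28.07% had an unadjusted p under 0.05, against a median of 8.77% and a highest value of 26.3% over 10567 runs of as many neighbouring genes. Genes of the stretch that vary between any libraries stay open, since 18.57% of its 70 tested genes had an unadjusted injection p under 0.05 (percentile 81.2 of 10470 runs, median 14.3%) and 2 passed for injection where 0.504 would fall there by number, and an effect of the genotype itself stays open, untested.

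Irf4 had more counts in the libraries labelled Irf4-/-. B cells and plasma cells as the whole source were argued against, since the summed log2 ratio of their markers with a mean below that of Irf4 was 0.725 (upper bound 0.913) and -1.336 in the injected pair and 0.098 (upper bound 0.224) and 0.15 in the control pair, below the lower bounds for Irf4 of 1.62 and 1.04, although the B cell list medians of 0.49 and 0.20 went the way of Irf4. T cells as the whole source were argued against, since the 12 T cell markers with a mean below that of Irf4 gained together -3.77 CPM in the injected pair and 0.02 in the control pair, where Irf4 alone gained 9.61 and 7.31, although Foxp3, which is among them, rose by 2.73. Neither this sum nor those of B and plasma cell markers can exclude a small subset rich in Irf4, whose gain other markers would mask. Dendritic cells and other innate lymphoid cells as a source were not tested. Of the dendritic cell list 0 of 10 tested genes rose with the genotype label, and 4 adjusted over the list alone. Of the other innate lymphoid list 2 of 8 rose. A swap within 1 pair was argued against by 0 genes at least 2-fold apart in both pairs with opposite signs among those with a mean of at least 5 CPM in each (genes such as Trnp1 lie below that mean in the control pair), where 43 were higher and 6 lower in both. Genotype labels exchanged in both pairs, under which an Irf4 change of 1.72 would be one toward fewer counts in the knockout, and a transcript of the targeted allele that is still counted, with at least 188 counts in each library so labelled, cannot be told apart, because gene-level counts do not show which exons were read. A biological rise of transcript from the Irf4 locus stays open, untested.

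Heat shock genes were lower in both injected libraries, with a median of -1.87 over 6 members in WT and -1.19 in mice labelled Irf4-/-. If handling of the tissue had moved immediate early genes with them, these would be lower too; their median over 16 members was 0.015 (-0.27 to 0.40) in WT and -0.038 in mice labelled Irf4-/-, with members going both ways, which does not decide it. A handling time or warmth that differed between control and injected mice and acted on heat shock genes could give the Hspa1b change of -5.80. It cannot be told apart from an effect of the injection, because the labels give no handling day and each injection state could have its own. The control libraries also differed from each other, with Hspa1b at 99.2 CPM in WT control and 24.2 in Irf4-/- control. In the injected libraries it was at 0.969 in WT and 1.02 in Irf4-/-. Hspa1b was the 1 gene of its list of 22 to fall with the genotype label in the additive model.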

How the results depend on the processing

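The alternatives without the other-cell and heat shock lists, and without the first 10 Mb of chromosome 11, were chosen only after the results were seen. No paired analysis was possible because each group has 1 library and no second replicate number to use as a block, so that only the other factor enters the additive model as a block, and no library could be left out, since no residual degrees of freedom would remain. Scaling, prior count, FPKM and leaving out abundant families kept every pair count within 1.5 times its value. The factors of the scaling methods lay between 0.993 and 1.01. FPKM ratios equal those of total scaling apart from the pseudocount. Other scalings and FPKM could therefore move the values little, and the tallies of list medians and pairwise values below include them. Of 1080 alternative list medians 1075 stayed within their interval. Of 3525 alternative pairwise values of named genes 3511 stayed within their counting interval with 0 reversed. Of 543 alternative values of named genes in the additive model 461 kept their direction and side of the threshold. The other 82 lost their call, 61 of them with the other term left out. Of the 461, 64 come from the adjusted p under 0.1, which uses the same fit and keeps every call by construction. Depth limits low genes, since a count of 0 allows up to 0.189 CPM in the library with the lowest total.

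The pair counts move by construction with the minimum and the fold. In the order genotype in injected mice, genotype in control mice, injection in WT and injection in mice labelled Irf4-/-, genes higher and lower were 38 and 28, 16 and 4, 34 and 28, and 4 and 6 at a minimum of 20 CPM. With no minimum they were 492 and 462, 433 and 214, 736 and 525, and 253 and 350. At a fold of 1.5 they were 395 and 288, 180 and 64, 403 and 408, and 142 and 116, and at a fold of 4 they were 24 and 8, 7 and 5, 5 and 4, and 0 and 4. Without the other-cell and heat shock lists injection in mice labelled Irf4-/- gave 8 and 13. Genes at least 2-fold apart in both genotype pairs were 11 higher and 3 lower at a minimum of 20 CPM, and 72 and 14 at 1; in both injection pairs they were 1 and 4, and 27 and 30. The responses that differed between genotypes were 7 higher and 24 lower at 20, and 194 and 332 at 1.

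At the minimum of 20 CPM the monocyte and macrophage median turned from 0.57 to -0.264 for genotype in control mice, and stood at 0.044 for injection in WT and 0.111 in mice labelled Irf4-/-; the B cell median stood at -0.270 in WT and -0.068 in mice labelled Irf4-/-. Fewer members are left there by construction, and the minimum of 5 members per list was not applied. The plasma cell list, for example, had 2 members with a mean of at least 5 CPM in each pair. Low markers are the ones dropped, so a median nearer 0 there does not show that other cells were absent.

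In the additive model, median-of-ratios scaling gave 261 higher and 113 lower for genotype and 230 and 228 for injection, and no filter gave 319 and 163, and 305 and 299, with all 177 and 87 original calls kept. The estimated prior degrees of freedom went from 9.62 to 33.5 with that scaling and to infinity with no filter, and whether this set the counts was not tested. A filter of 5 CPM (prior 11.8) gave 75 and 86 for injection, and an adjusted p under 0.1 gave 114 and 121. DESeq2 gave 15 lower for genotype, and the cause was not tested. With the other term left out genotype gave 3 and 2 and injection 0 and 0, as the effect left out then counts as error. Without the first 10 Mb of chromosome 11 genotype gave 133 and 25, and without the other-cell and heat shock lists 150 and 29.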

Other observations

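The genes and libraries here were chosen after their values were seen, as was the crossed split of the libraries. Foxp3, the regulatory T cell factor, rose with the genotype label by 2.73 (SE 0.494), from 6 and 8 counts in WT to 44 and 38, with an adjusted p of 0.0213 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and 0.122 in DESeq2, while the T cell list had genotype medians of -0.02 in control and -0.03 in injected mice. Nnt (the gene at chromosome 13, 119335448 to 119408997 in GRCm38) rose by 1.09 (SE 0.142). It is a mitochondrial transhydrogenase gene in which the C57BL/6J substrain is known to carry a deletion. Its counts were 503 and 351 in WT control and injected and 698 and 871 in the libraries labelled Irf4-/-.

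Gm26917 and Gm42418, neighbouring noncoding genes on chromosome 17 known to collect reads of ribosomal RNA, took 27630 and 64226 counts in WT control. With the genotype label Gm26917 fell by 1.14 and Gm42418 fell by 0.86, with adjusted p of 0.359 and 0.953 in DESeq2, and with injection Gm26917 fell by 2.44 (SE 0.188).

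The WT injected library stood apart from the others, with an SD of the log2 difference of 0.361 to WT control, 0.399 to Irf4-/- control and 0.359 to Irf4-/- injected, where the pairs without it gave 0.247, 0.325 and 0.234. The crossed split, which sets WT control and Irf4-/- injected against the other 2 libraries, gave 0 genes in edgeR with either term added, with 80 and 112 genes at an unadjusted p under 0.05 and 0 in limma-voom. With genotype added the injection effect counts as error there, and with injection added the genotype effect does. The split therefore cannot decide whether responses differ between genotypes, and it gives no null level for the other splits. With 1 library per group the splits are too few to give a share under 0.05.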
